A study of Homo sapiens with 12 samples.

How the data were processed

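Bulk RNA sequencing of 12 libraries of MIO-M1 cells was analysed, taken 3 days after siRNA transfection, in 2 experiments of 6 libraries, each with 3 knockdown libraries and 3 libraries of its own control siRNA. Per the labels, RNA was extracted with TRIzol, polyadenylated RNA was captured on oligo(dT) and cDNA was primed with random hexamers; the strand of the libraries is not stated. The submitters' processing notes name Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCh38.p14 without saying which step each served; annotation and filters are not stated. The authors deposited 1 table per experiment, with 17598 and 17146 genes (16752 in both), and each library has its own columns.

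The deposited read counts are expected counts per gene (RSEM's estimated fragments, not normalized); 85.5% to 91.8% of the values per library were whole numbers as written, with no tolerance. The authors' FPKM values, normalised per kilobase of effective transcript length and per-million fragments, served only to derive an effective length per gene as count over FPKM, for the 14034 genes with a count of at least 10 and an FPKM of at least 0.2. The median absolute log2 deviation of a library's length from the gene's median was 0.0141. A further 24 per-library columns were not used, and single-cell data that the series describes were not analysed here.

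Total counts were 31040067 to 31510571 in the control libraries, 14516406 to 19463837 in siMAPK14 and 9246294 to 20136463 in siMAPK8_9. 1 count equals 0.0317 CPM in the deepest library and 0.108 CPM in the shallowest, and a count of 0 allows up to 3 counts, or 0.0952 to 0.324 CPM. Shares of counts in a single library carry 95% Wilson intervals; intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

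Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and each experiment was fitted alone by robust quasi-likelihood with an F-test of knockdown against its own control. The difference between the knockdown effects was tested in 1 fit of all 12 libraries, as the siMAPK14 effect minus the siMAPK8_9 effect; levels of control and knockdown groups across experiments come from the same fit. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. CPM are TMM-scaled; per-library levels of epithelial markers are CPM over nuclear-encoded counts.

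A total of 33 gene lists was fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The lists cover the p38 and JNK pathways, retinal and other cell types, the cell cycle, signalling targets, matrix, inflammation, stress responses, metabolism and the mitochondrial and cytosolic ribosomal genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. List counts are of genes past the threshold over all genes and, separately, adjusted over the list alone. Named genes are the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 10 CPM and no overlap of the groups' libraries (6 and 6 for the difference), a fixed set of genes of interest, up to 4 genes past the threshold per list by smallest adjusted p, and up to 2 of the most abundant others of the Müller glia, gliosis, progenitor and AP-1 lists. With 3 libraries against 3, chance gives 10% of genes no overlap.

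Alternatives were RLE and upper-quartile factors, total counts, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, a minimum fold of 1.2 (glmTreat), a joint fit, and leaving out each library. Added after the data were seen were the removal of lowess trends (span 0.3) on effective length or on transcript GC content within each library, thinning to 1 depth, and leaving out the 13 mitochondrially encoded genes. The expression levels of 46 epithelial marker genes were tested from a list written after 6 of them had been seen. Other splits of the libraries were refitted, with 100 drawn where more exist. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

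The pipeline was tested on simulated data made from the mean levels of the controls and the fitted dispersions, with 200 changed genes, 67 each at 1.5-fold and 2-fold and 66 at 4-fold. Of the 67 at 2-fold it recovered 83.6% for siMAPK14, 35.8% for siMAPK8_9 and 28.4% for the difference, and of the 67 at 1.5-fold 58.2%, 0% and 0%, with 8, 3 and 8 unchanged genes called. Both simulated groups shared 1 dispersion per gene, and far fewer genes changed than the 59.9% and 52.9% called in siMAPK14 and siMAPK8_9. The recovered shares and false calls therefore need not hold for the real comparisons. Camera found the 1 shifted list and called 0 others in each comparison. The simulated genes were drawn independently of each other, so this does not show how camera behaves for lists with correlated members. In simulations with a length slope of -0.5, trend removal took r of fold change and length from -0.878 to -0.0052 (siMAPK14) and from -0.827 to -0.0053 (siMAPK8_9).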

Results

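Messenger RNA was sequenced from MIO-M1 cells, a human Müller glia cell line, 3 days after transfection of small interfering RNA (siRNA). Müller glia are the main glial cells of the retina. In 1 experiment an siRNA against MAPK14 (siMAPK14), the gene of the kinase p38-alpha, was set against a control siRNA, and in the other siRNAs against MAPK8 and MAPK9 together (siMAPK8_9), the genes of the kinases JNK1 and JNK2, were set against a control siRNA of their own. Each of the 4 groups held 3 libraries, so 12 libraries in all, and the labels give the 2 experiments different batches. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries. The stated purpose was to find which downstream signalling genes change after loss of p38-alpha or of JNK1 and JNK2. Unless stated otherwise, values are mean ± SD of CPM (counts scaled by TMM to a common library size) over 3 libraries, log2 fold changes carry their standard error, and adjusted p-values come from edgeR.

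The libraries of the knockdown groups differed from the controls in depth and in the kind of RNA counted. Control libraries held 31040067 to 31510571 counts, siMAPK14 libraries 14516406 to 19463837, and siMAPK8_9 libraries 10072307, 20136463 and 9246294. The 13 protein-coding genes of the mitochondrial genome took 1.56% to 2.03% of counts in the control libraries, 39.4% ± 6.61 (SD, n = 3) in siMAPK14 and 26.9% ± 15.6 (SD, n = 3) in siMAPK8_9. In siMAPK8_9 replicate 2 the share was 8.93% (95% Wilson interval 8.91% to 8.94%), against 36.9% and 35.0% in replicates 1 and 3. Genes of the cytosolic ribosome took 3.17% to 3.78% of the nuclear-encoded counts in the controls and 5.72% to 9.39% in the knockdown libraries. Replicate 2 of siMAPK8_9 also held transcripts of epithelial keratins: KRT14 was at 409 CPM of nuclear-encoded counts there and at most 0.666 CPM in the other 11 libraries. Fold changes ran with transcript length in both knockdowns. In siMAPK14 the median log2 fold change went from 0.73 in the fifth of genes with the shortest transcripts to -0.57 in the fifth with the longest, and in siMAPK8_9 from 0.97 to -0.78. These library traits accompany every gene group below, and values with the length trend removed are given beside many of them.

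**Figure D1:**
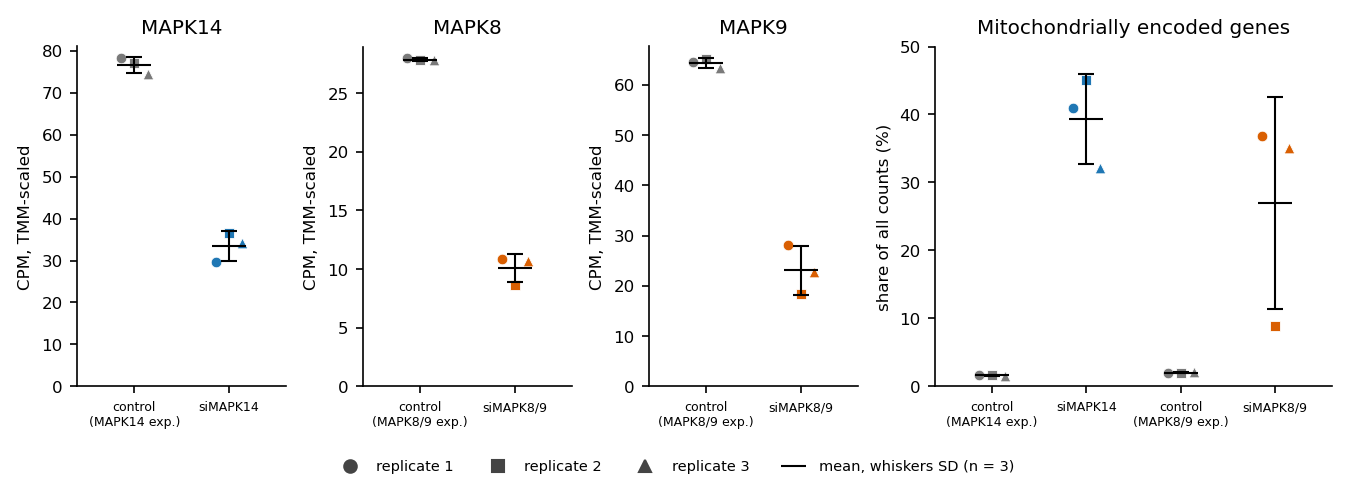
Each point is 1 library, with the group mean and SD: the first panels show MAPK14, MAPK8 and MAPK9 (TMM-scaled CPM) and the last the share of all counts from the 13 mitochondrially encoded genes (%). MAPK14 averaged 33.5 CPM in siMAPK14 against 76.7 CPM in its control, and the mitochondrial share of siMAPK8_9 replicate 2 was 8.93% against 36.9% and 35.0% in the other replicates.

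Each target was lower after its siRNA. MAPK14 (gene ID 1432; GRCh38.p14 chromosome 6, from 36027808 to 36124214) fell from 76.7 ± 1.95 to 33.5 ± 3.53 CPM in siMAPK14, 43.6% of its control (log2 fold change -1.20 ± 0.09, adjusted p = 9.95e-06). MAPK8 (gene ID 5599; chromosome 10, from 48306677 to 48439360) fell from 27.9 ± 0.12 to 10.1 ± 1.22 CPM in siMAPK8_9, 36.1% of control (-1.48 ± 0.14, adjusted p = 0.000667). MAPK9 (gene ID 5601; chromosome 5, from 180233143 to 180292083) fell from 64.4 ± 0.94 to 23.1 ± 4.83 CPM, 35.9% of control (-1.49 ± 0.17, adjusted p = 0.00103). With the length trend removed the changes were -0.93 for MAPK14, -0.80 for MAPK8 and -1.01 for MAPK9, all still past the threshold.

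Other members of the kinase family changed too. MAPK11, the gene of p38-beta (gene ID 5600; chromosome 22, from 50263713 to 50270380), fell in siMAPK14 from 5.43 ± 0.41 to 1.26 ± 0.19 CPM (-2.11 ± 0.24, adjusted p = 8.11e-05). MAPK8 and MAPK9 did not pass the test in siMAPK14, with log2 fold changes of -0.01 ± 0.09 and -0.07 ± 0.08. MAPK9 passed without siMAPK14 replicate 3 (-0.16, adjusted p = 0.0400). MAPK14 fell in siMAPK8_9 to 66.1% of control (-0.60 ± 0.17, adjusted p = 0.0258). That call ended when siControl_MAPK8_9_set replicate 1, 2 or 3 was left out (adjusted p = 0.0819, 0.0713 and 0.0748) and with the length trend removed (-0.21, adjusted p = 0.367). MAPK13 rose in siMAPK8_9 from 1.395 ± 0.26 to 4.60 ± 3.01 CPM (1.76 ± 0.53, adjusted p = 0.0292), and without siMAPK8_9 replicate 2 the change was 1.12 (adjusted p = 0.0588); without siMAPK8_9 replicate 3 it was 1.82 (adjusted p = 0.0556), and without siControl_MAPK8_9_set replicate 1, 2 or 3 the adjusted p was 0.111, 0.0862 or 0.0866. MAPK12 passed in neither experiment. Of 25 genes of the p38 pathway 6 rose and 8 fell in siMAPK14 and 7 rose and 6 fell in siMAPK8_9 (the same counts adjusted over the list alone; camera adjusted p = 0.669 and 0.753), and 8 and 5 and 11 and 5 with the length trend removed. Of 20 genes of the JNK pathway 3 rose and 10 fell in siMAPK14 and 4 rose and 4 fell in siMAPK8_9 (the same counts adjusted over the list alone; camera adjusted p = 0.210 and 0.610). With the length trend removed 5 rose and none fell in siMAPK14, where the list median went from -0.32 to -0.02, and 6 rose and 2 fell in siMAPK8_9, where it went from -0.36 to 0.16. Leaving out siMAPK8_9 replicate 2 gave 8 higher and 9 lower for the p38 list and 4 and 11 for the JNK list (median -0.45) in siMAPK8_9. MAP2K3, a kinase that activates p38, rose in siMAPK14 (0.76 ± 0.09), and MAP2K6, another, fell in siMAPK8_9 (-2.93 ± 0.29; -1.83 with the length trend removed).

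After MAPK14 knockdown, genes of the extracellular matrix were among those with the largest falls. COL1A1, a chain of collagen I, fell from 817 ± 61.1 to 102 ± 18.7 CPM (-3.00 ± 0.13, adjusted p = 2.7e-06), and COL6A3, a chain of collagen VI, from 27.6 ± 1.89 to 1.64 ± 0.77 CPM (-4.11 ± 0.24, adjusted p = 5.07e-06). The proteoglycan genes VCAN (versican) and HSPG2 (perlecan) fell by 3.03 and 3.13 on the log2 scale, and IGFBP5, which binds insulin-like growth factors, fell by 2.70. The other genes with the largest falls were MXRA5 (-3.63 ± 0.39), APLN, which encodes the peptide apelin (-3.32 ± 0.44), PODXL, a cell surface sialomucin (-3.14 ± 0.25), ENPP1, an ectonucleotidase (-3.14 ± 0.12), and NEURL1B (-3.05 ± 0.36). Of the 37 TGF-beta target and matrix genes, 35 fell and none rose, with the same 35 adjusted over the list alone, and a median log2 fold change of -1.56 (-1.15 with the length trend removed; camera adjusted p = 8.71e-12, and adjusted p = 0.568 with an estimated correlation). Targets of YAP and TAZ, the co-activators of the Hippo pathway, fell in 18 of 25 cases and rose in 2 (18 and 2 adjusted over the list alone). NT5E fell by 1.49 and TEAD1 by 1.36, and GADD45B rose by 1.62. Their median was -0.95, and -0.39 with the length trend removed (camera adjusted p = 0.000144, and adjusted p = 0.505 with an estimated correlation). TEAD1 stood at -0.69 and GADD45B at 1.02 with that trend removed.

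Cell cycle genes fell in siMAPK14. Of 54 genes of the G2 and M phases, 46 fell and 3 rose (46 and 3 adjusted over the list alone), with a median of -0.82. TOP2A, the DNA topoisomerase of dividing cells, fell from 352 ± 35.0 to 78.7 ± 7.77 CPM (-2.16 ± 0.10, adjusted p = 2.7e-06), and ANLN, needed for cytokinesis, by 1.54. The list passed camera at adjusted p = 2.05e-10, with adjusted p = 0.505 with an estimated correlation. Of 42 genes of the G1 to S transition 23 fell and 4 rose (23 and 6 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0110, 0.0527 without siMAPK14 replicate 3, and adjusted p = 0.613 with an estimated correlation). UHRF1, which maintains DNA methylation, fell by 1.86 on the log2 scale, and CCND1, the gene of cyclin D1, from 311 ± 23.8 to 144 ± 24.7 CPM (-1.11 ± 0.12, adjusted p = 6.43e-05).

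Growth factor, hypoxia and interferon genes were lower as well. Among 29 receptor tyrosine kinases and their ligands, 19 fell and 2 rose (19 and 3 adjusted over the list alone), with EGFR at -1.06 ± 0.06, MET at -1.44 ± 0.14 and TGFA, an EGFR ligand, at -2.13 ± 0.20. The median was -0.72 and -0.42 with the length trend removed (camera adjusted p = 0.00278, and adjusted p = 0.568 with an estimated correlation); EGFR then stood at -0.39 and MET at -0.94. Of 35 genes of glycolysis and the hypoxia response, 23 fell and 5 rose (the same counts adjusted over the list alone), median -0.41. Among them the glucose transporter SLC2A1 fell from 492 ± 60.3 to 205 ± 31.3 CPM (-1.26 ± 0.12) and the lactate transporter SLC16A3 by 1.59. Camera gave adjusted p = 0.00644, and adjusted p = 0.568 with an estimated correlation. Of 37 interferon-stimulated genes 20 fell and 3 rose (the same counts adjusted over the list alone), with the antiviral gene RSAD2 at -2.21 ± 0.13 and IFIT2 at -2.09 ± 0.14. Their median was -0.40 (camera adjusted p = 0.00644, and adjusted p = 0.568 with an estimated correlation).

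The genes that rose in siMAPK14 were led by the mitochondrial genome, whose 13 genes all rose (13 adjusted over the list alone) with a median log2 fold change of 5.48. MT-ATP6, a subunit of ATP synthase, went from 668.5 ± 53.05 to 48980 ± 12690 CPM (6.20 ± 0.23, adjusted p = 2.66e-06). MT-COX2 rose by 6.16, MT-ND4 by 5.80, MT-ND1 by 5.77, MT-ATP8 by 5.70, MT-CYTB by 5.54, MT-ND3 by 5.48, MT-COX3 by 5.46, MT-ND2 by 5.43 and MT-ND4L by 4.94. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4, so reads of those pairs cannot be assigned with certainty, and with the length trend removed MT-ATP8 stood at 3.62. The mitochondrial list passed camera at adjusted p = 8.1e-10, with adjusted p = 0.505 with an estimated correlation. All 52 cytosolic ribosomal protein genes rose (52 adjusted over the list alone), with a median of 1.12 that was 0.24 with the length trend removed, when 32 rose and 1 fell (camera adjusted p = 9.9e-18, and adjusted p = 0.568 with an estimated correlation). Of the 34 nuclear genes of oxidative phosphorylation 32 rose (32 and 1 lower adjusted over the list alone), with a median of 1.02, or 0.19 with the length trend removed (camera adjusted p = 1.89e-11, and adjusted p = 0.505 with an estimated correlation). Of 16 heat shock genes 14 rose and none fell (the same adjusted over the list alone), with a median of 0.59 that was 0.30 with the length trend removed and -0.19 under total-count scaling, 0.60 above the median of all genes there (camera adjusted p = 0.000145, and adjusted p = 0.505 with an estimated correlation). BAG3, a co-chaperone, rose by 0.78, and HSPB1, a small heat shock protein whose kinase is activated by p38, rose by 1.05 but stood at 0.11 (adjusted p = 0.138) with the length trend removed.

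Stress response genes changed in both directions in siMAPK14. ATF3, a transcription factor induced by stress, rose from 49.9 ± 6.95 to 200.2 ± 33.3 CPM (2.00 ± 0.14, adjusted p = 7.9e-06), and FOS, an AP-1 subunit, from 5.06 ± 0.11 to 15.3 ± 1.59 CPM (1.60 ± 0.14, adjusted p = 2.23e-05). KLF6 and FOSL2 of the same list fell by 0.89 and 1.18 (by 0.53 and 0.65 with the length trend removed). JUN was at -0.14 ± 0.12 and DUSP1, a phosphatase of p38 and JNK, at 0.06 ± 0.07, neither past the threshold; JUN passed without siMAPK14 replicate 3 (-0.31, adjusted p = 0.00745). Of 27 AP-1 and immediate-early genes 10 rose and 7 fell (the same counts adjusted over the list alone), and the list did not pass camera (adjusted p = 0.368). Of 29 genes of the unfolded protein response and of ATF4, a transcription factor of amino acid and protein folding stress, 17 rose and 8 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0682); with the length trend removed 13 rose and 9 fell, and the median went from 0.35 to 0.03. DDIT3, the gene of the stress factor CHOP, rose by 1.61 and ATF4 by 0.99, and with the length trend removed by 0.77 and 0.41.

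Marker genes of Müller glia and of retinal reprogramming changed in both directions in siMAPK14. Of 18 Müller glia markers 7 rose and 8 fell (the same counts adjusted over the list alone; median -0.25, mean 0.30, camera adjusted p = 0.987). With the length trend removed 8 rose and 6 fell, and the median was 0.26. CLU rose by 1.88 ± 0.07 and SPP1 by 1.65 ± 0.12, whereas NFIX fell by 1.60 ± 0.10, TIMP3 by 2.15 ± 0.13 and SOX9, a glial and progenitor transcription factor, by 0.71 ± 0.14 (by 0.46 with the length trend removed). GLUL, the glutamine synthetase of Müller glia, was at -0.22 ± 0.06 (adjusted p = 0.00789), and at 0.37 (adjusted p = 0.00125) with the length trend removed, so its direction turned. Of 30 genes of reactive gliosis 11 rose and 11 fell (the same counts adjusted over the list alone; camera adjusted p = 0.866), with HMOX1 at 1.19 ± 0.09 (0.68 with the length trend removed). With that trend removed 4 rose and 12 fell, the median went from 0.08 to -0.19, and camera gave adjusted p = 0.0571. The intermediate filament gene VIM was at 0.19 ± 0.09 and STAT3 at -0.23 ± 0.10, neither past the threshold; VIM passed under DESeq2 and limma-voom (adjusted p = 0.0142 and 0.0273) and without siMAPK14 replicate 3 (0.24, adjusted p = 0.00734), and STAT3 under limma-voom and with the replicate block (adjusted p = 0.0347 and 0.0326) and without siMAPK14 replicate 1 (-0.35, adjusted p = 0.00878). GFAP was at 0.60 CPM in the control and 0.67 CPM in the knockdown (adjusted p = 0.852). Of 10 measured genes of retinal progenitors and neurogenesis 4 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.577), and 2 and 1 with the length trend removed. The fall was in NES, the gene of nestin (-1.08 ± 0.09, and -0.62 with the length trend removed). GADD45G rose by 2.45 ± 0.27 and HMGA1 by 0.88 ± 0.08 (0.54 with that trend removed). PAX6 was at 0.48 ± 0.14 (adjusted p = 0.0167), a call that ended without siControl_MAPK14_set replicate 2 or 3 (adjusted p = 0.104 and 0.0648) and with the length trend removed (0.35, adjusted p = 0.0771). SOX2 was at 0.20 ± 0.17 (adjusted p = 0.355).

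In the test of all genes, 7899 of 13183 (59.9%) passed an adjusted p of 0.05 in siMAPK14, 3876 higher and 4023 lower, of which 2422 differed at least 2-fold. Removal of the length trend gave 6060 (3194 higher and 2866 lower), of which 4796 were among the 7899 and 4522 of those had the same direction. Under total-count scaling, which takes the mitochondrial counts into every library size, it was 9084 with 729 higher and 8355 lower, because the median of all genes lay at -0.79.

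After knockdown of MAPK8 and MAPK9, genes of the integrated stress response rose against the control of that experiment. DDIT3 rose from 23.7 ± 0.0892 to 369 ± 61.9 CPM (3.96 ± 0.16, adjusted p = 9.69e-05), DDIT4, an inhibitor of mTORC1, from 33.1 ± 0.82 to 492 ± 62.0 CPM (3.89 ± 0.14, adjusted p = 9.69e-05), and TRIB3 and ASNS, both ATF4 targets, rose by 2.88 ± 0.15 and 1.97 ± 0.10. Of the 29 genes of the unfolded protein response and ATF4, 22 rose and 2 fell (the same counts adjusted over the list alone) with a median of 1.38. Camera gave adjusted p = 3.74e-07, and adjusted p = 0.706 with an estimated correlation. GDF15, a stress-induced cytokine, rose from 1.44 ± 0.35 to 81.8 ± 33.0 CPM (5.83 ± 0.37, adjusted p = 0.000269), and ARG2, the mitochondrial arginase, from 2.21 ± 0.37 to 72.2 ± 15.6 CPM (5.03 ± 0.23, adjusted p = 0.00012). Without siMAPK8_9 replicate 2 the list's counts were 22 and 6. In a joint fit the control of siMAPK8_9 lay below that of siMAPK14 by a median of 0.77 log2 units for this list. The knockdown groups (siMAPK14 minus siMAPK8_9) differed by 0.04 there. DDIT4 averaged 537 CPM in the control of siMAPK14, 337 in siMAPK14, 32.8 in the control of siMAPK8_9 and 480 in siMAPK8_9.

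Immediate-early and inflammatory genes rose in siMAPK8_9 against its own control. In a joint fit that control lay below the control of siMAPK14 by medians of 1.25 and 1.18 log2 units for these lists. The knockdown groups (siMAPK14 minus siMAPK8_9) differed by -0.05 and 0.06. Of 26 AP-1 and immediate-early genes 17 rose and none fell (the same adjusted over the list alone; 17 and 3 without replicate 2), with a median of 1.06 (camera adjusted p = 1.8e-05, and adjusted p = 0.720 with an estimated correlation). ATF3 rose by 3.56 ± 0.25, DUSP1 from 44.0 ± 0.83 to 326 ± 17.0 CPM (2.89 ± 0.11, adjusted p = 9.69e-05), FOS by 2.78 ± 0.27, ZFP36, which promotes decay of inflammatory mRNAs, by 2.39 ± 0.12 and DUSP4 by 1.98 ± 0.14. JUN, whose product is the substrate from which JNK has its name, was at 0.44 ± 0.25 (adjusted p = 0.180). Of 30 inflammatory and NF-kB genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; 18 and 5 without replicate 2). IL1A rose by 5.62 ± 0.51 from 0.083 CPM, a level of a few counts per library, so the size of that rise is uncertain. RELB and NFKBIA, parts of the NF-kB pathway, rose by 1.70 ± 0.19 and 1.31 ± 0.16 (NFKBIA by 0.67 with the length trend removed). The list median was 1.24, 0.60 without replicate 2 (camera adjusted p = 0.000382, 0.0162 without replicate 2, and adjusted p = 0.720 with an estimated correlation).

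Genes of glycolysis and the hypoxia response rose in siMAPK8_9, in 22 of 35 cases with none lower (23 and none adjusted over the list alone; 24 and 7 without replicate 2). ANKRD37 rose by 3.72 ± 0.17, the oxygen sensor gene EGLN3 from 18.5 ± 0.0994 to 140 ± 50.1 CPM (2.93 ± 0.25, adjusted p = 0.000482), and the mitophagy receptor genes BNIP3 and BNIP3L by 2.04 ± 0.13 and 1.43 ± 0.10. The median was 1.02, and 0.67 without replicate 2 (camera adjusted p = 1.7e-05, and adjusted p = 0.720 with an estimated correlation). In the joint fit the control of siMAPK8_9 lay below that of siMAPK14 by a median of 0.56 log2 units for this list. The knockdown groups (siMAPK14 minus siMAPK8_9) differed by -0.62. In the mitochondrial genome 12 of 13 genes rose (12 adjusted over the list alone), with a median of 4.34; MT-COX2 rose by 5.72 ± 0.82, MT-ATP6 by 4.91 ± 0.75, MT-ND4 by 4.85 ± 0.77, MT-COX3 by 4.81 ± 0.76 and MT-ND1 by 4.80 ± 0.76. That list passed camera at adjusted p = 9.49e-05, with adjusted p = 0.720 with an estimated correlation. All 52 ribosomal protein genes rose (52 adjusted over the list alone), with a median of 1.58 that was 0.39 with the length trend removed (camera adjusted p = 4.33e-15, and adjusted p = 0.720 with an estimated correlation). Of 34 nuclear oxidative phosphorylation genes 32 rose (33 adjusted over the list alone), with a median of 1.34, or 0.33 with the length trend removed (camera adjusted p = 2.9e-09, and adjusted p = 0.720 with an estimated correlation).

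Matrix genes fell in siMAPK8_9, and more cell cycle genes fell than rose. Of 37 TGF-beta target and matrix genes 21 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -1.32; with the length trend removed 11 fell and 1 rose, with a median of -0.85. Without replicate 2, 36 fell and 1 rose, with a median of -1.89. COL4A1 fell by 2.42 ± 0.33 and COL5A1 by 2.48 ± 0.39 (by 1.63 with the length trend removed). The list passed camera at adjusted p = 3.23e-05, with adjusted p = 0.720 with an estimated correlation. Targets of YAP and TAZ fell in 14 of 25 cases and rose in 3 (14 and 3 adjusted over the list alone), with CCN1 at -1.78 ± 0.23; their median was -0.94, and -0.29 with the length trend removed, which ended the call (camera adjusted p = 0.0255, 0.355 with that trend removed, 0.0678 without replicate 1, 0.0581 without replicate 3, and adjusted p = 0.720 with an estimated correlation). Of 54 G2 and M phase genes 24 fell and 6 rose (the same counts adjusted over the list alone), with the kinesin gene CENPE at -2.33 ± 0.14 and TOP2A at -1.81 ± 0.17 (-1.47 and -1.17 with the length trend removed). Of 42 G1 to S genes 24 fell and 5 rose (25 and 5 adjusted over the list alone), with UHRF1 at -2.08 ± 0.15. Camera gave adjusted p = 0.0063 for G2 and M and 0.00769 for G1 to S, with adjusted p = 0.720 with an estimated correlation for both. Without replicate 2 these were 0.157 and 0.133, and both calls ended. Without that library both lists were more mixed: 27 fell and 14 rose for G2 and M, and 25 fell and 11 rose for G1 to S. The list medians changed little, from -0.29 to -0.30 and from -0.53 to -0.50. CCND1 fell from 398 ± 18.9 to 159 ± 84.0 CPM (-1.32 ± 0.35, adjusted p = 0.0184); the adjusted p was 0.0505 without siControl_MAPK8_9_set replicate 2, 0.0531 without siControl_MAPK8_9_set replicate 3 and 0.0720 without siMAPK8_9 replicate 3.

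The genes with the largest falls in siMAPK8_9 were HMCN1, the matrix protein hemicentin (-3.84 ± 0.60), LZTS1 (-3.58 ± 0.36), the atypical cadherin gene FAT3 (-3.54 ± 0.38; -2.31 with the length trend removed), ZNF469 (-3.53 ± 0.24), KIAA1549L (-3.52 ± 0.37) and the peptidase inhibitor PI15 (-3.48 ± 0.21). LPAR4, a receptor of lysophosphatidic acid, fell by 3.38, GUCY1A2, a guanylate cyclase subunit, by 3.32 (by 2.12 with the length trend removed), LSAMP, a neural adhesion molecule, by 3.30 and FNDC1 by 3.20. Among the 10 largest rises, 2 owed much of their size to replicate 2. SERPINB5, an epithelial serpin, was at 41.2 ± 70.4 CPM against 0.299 ± 0.0440 (7.13 ± 2.06, adjusted p = 0.0251), and at 0.85 (adjusted p = 0.244) without that library. It did not pass under limma-voom or with the replicate block (adjusted p = 0.116 and 0.106). The keratin gene KRT8 was at 5.22 ± 1.44 (adjusted p = 0.0206), and at 1.85 (adjusted p = 0.00368) without replicate 2; its call ended without siControl_MAPK8_9_set replicate 1, 2 or 3 (adjusted p = 0.0722, 0.0683 and 0.0720), under limma-voom (0.0617) and with the replicate block (3.52, adjusted p = 0.0595). EIF3CL rose by 5.61 ± 0.80, but its sequence is nearly that of EIF3C, so its reads cannot be assigned with certainty. In replicate 2 the epithelial genes KRT14, KRT17, KRT5 and KRT8 were at 409, 292, 240 and 187 CPM of nuclear-encoded counts.

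**Figure D2:**
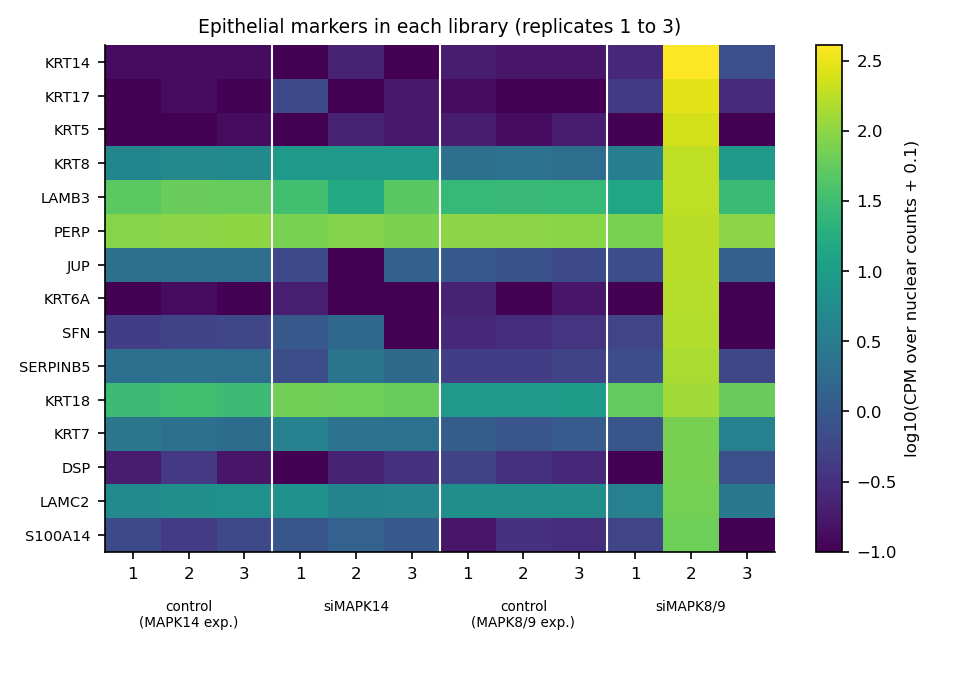
Heat map of 15 epithelial marker genes (lines) in each library (columns), coloured by the log10 of CPM over nuclear-encoded counts plus 0.1. KRT14 reads 409 CPM in siMAPK8_9 replicate 2 and at most 0.666 CPM in the other libraries.

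Müller glia markers changed in both directions in siMAPK8_9 as well: 4 rose and 2 fell of 18 (the same counts adjusted over the list alone; 4 and 4 without replicate 2; camera adjusted p = 0.848). NFIX fell by 2.15 ± 0.25 and SOX2, a transcription factor of progenitors and Müller glia, from 15.9 ± 0.91 to 5.40 ± 2.08 CPM (-1.50 ± 0.27, adjusted p = 0.00437). GLUL rose by 0.49 ± 0.10 (adjusted p = 0.00657), 1.33 with the length trend removed; its adjusted p was 0.0522 without siControl_MAPK8_9_set replicate 2 and 0.0510 without siControl_MAPK8_9_set replicate 3. SOX9 was at -0.13 ± 0.29 (adjusted p = 0.720) and STAT3 at -0.36 ± 0.20 (adjusted p = 0.163), and both passed without siMAPK8_9 replicate 2 (-0.58, adjusted p = 0.000181, and -0.59, adjusted p = 0.00135). Of 31 reactive gliosis genes 12 rose and 6 fell (the same counts adjusted over the list alone; camera adjusted p = 0.157); with the length trend removed 6 rose and 3 fell, and the median went from 0.58 to 0.13. Without replicate 2 of siMAPK8_9, 12 rose and 11 fell, with a median of 0.21. The metallothionein genes MT1X and MT2A rose by 2.97 ± 0.17 and 1.97 ± 0.19, and with the length trend removed stood at 1.16 and 0.13, the latter not past the threshold (adjusted p = 0.503). VIM rose from 4234 ± 68.5 to 8481 ± 1881 CPM (1.00 ± 0.24, adjusted p = 0.0117), a call that ended without siControl_MAPK8_9_set replicate 1, 2 or 3 (adjusted p = 0.0648, 0.0640 and 0.0607). GFAP was at 0.324 CPM in the control and 0.817 CPM in the knockdown (adjusted p = 0.144). Of 10 progenitor and neurogenic genes 2 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.798; 1 and 1 with the length trend removed; 2 and 3 without siMAPK8_9 replicate 2), with GADD45G at 2.53 ± 0.35 (1.55 with the length trend removed), PAX6 at -0.03 ± 0.20 (adjusted p = 0.917) and NES at -0.89 ± 0.33 (adjusted p = 0.0582). NES passed under DESeq2 and limma-voom (adjusted p = 0.0231 and 0.0445), with the replicate block (-1.01, adjusted p = 0.0242) and without siMAPK8_9 replicate 2 (-1.34, adjusted p = 0.00056).

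**Figure D3:**
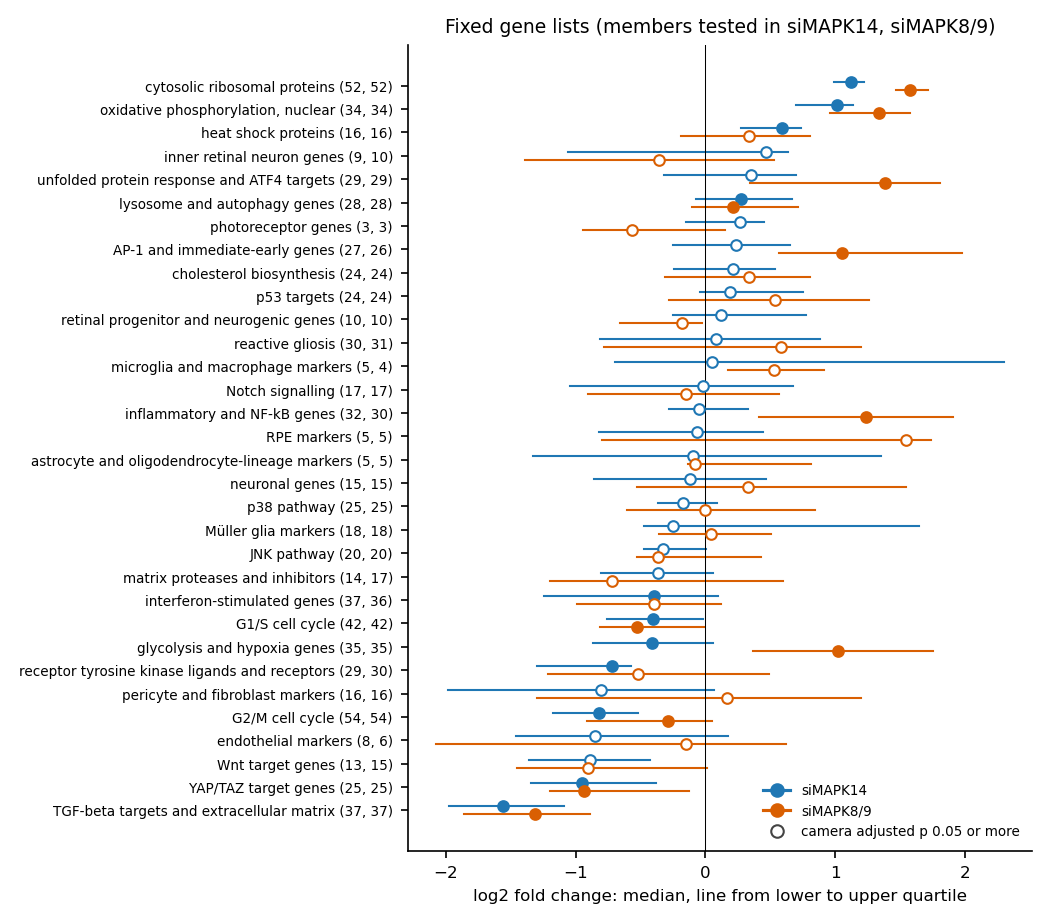
Median log2 fold change of each fixed gene list in both knockdowns (points), with lines from the lower to the upper quartile and filled points where camera passed an adjusted p of 0.05 with its preset correlation; the mitochondrial list is left out for scale. The matrix list lies at -1.56 and -1.32, and the glycolysis and hypoxia list at -0.41 in siMAPK14 and 1.02 in siMAPK8_9.

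In the test of all genes, 6938 of 13124 (52.9%) passed in siMAPK8_9, 3514 higher and 3424 lower, of which 3731 differed at least 2-fold. Without replicate 2 the count was 9554 (4514 higher and 5040 lower), and without siControl_MAPK8_9_set replicate 1, 2 or 3 it was 4509, 4560 or 4545. Removal of the length trend gave 4941 (2820 higher and 2121 lower), of which 3717 were among the 6938 and 3570 of those had the same direction. The count was 6036 under total-count scaling, with 1122 higher and 4914 lower and the median of all genes at -0.71.

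The effects of both knockdowns were then compared gene by gene, as the log2 fold change in siMAPK14 minus that in siMAPK8_9. The glycolysis and hypoxia list, lower in siMAPK14 and higher in siMAPK8_9, differed by a median of -1.46, with 27 of 35 genes past the test in that direction (31 adjusted over the list alone; camera adjusted p = 4.99e-18, and adjusted p = 0.135 with an estimated correlation). BNIP3 differed by -1.99 ± 0.14 and EGLN3 by -3.73 ± 0.29. The ATF4 and unfolded protein list differed in 16 of 29 genes, all in the same direction (18 adjusted over the list alone), median -0.97 (camera adjusted p = 3.9e-11, and adjusted p = 0.0966 with an estimated correlation), with DDIT4 at -4.54 ± 0.17 and TRIB3 at -2.04 ± 0.16. AP-1 and immediate-early genes differed in 17 of 27 cases, 15 of them lower (2 and 20 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 1.6e-08, and adjusted p = 0.454 with an estimated correlation) and DUSP1 at -2.85 ± 0.12. Inflammatory genes differed in 16 of 32, all lower (3 higher and 19 lower adjusted over the list alone), with a median of -1.17, or -0.59 without siMAPK8_9 replicate 2 (camera adjusted p = 3.71e-06, and adjusted p = 0.582 with an estimated correlation). Of 54 G2 and M genes 19 lay lower and 2 higher (27 and 2 adjusted over the list alone; 32 and 6 without siMAPK8_9 replicate 2), with a median of -0.54 (camera adjusted p = 4.51e-06, and adjusted p = 0.351 with an estimated correlation).

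Single genes with opposite changes included MMP3, a matrix protease, which rose by 2.28 in siMAPK14 and fell by 1.53 in siMAPK8_9 (difference 3.82 ± 0.60, adjusted p = 0.00144). Its fall in siMAPK8_9 did not pass without siMAPK8_9 replicate 1 (adjusted p = 0.0622) or without siControl_MAPK8_9_set replicate 1, 2 or 3 (adjusted p = 0.0791, 0.0717 and 0.0931). PEG10, an imprinted gene derived from a retrotransposon, rose by 0.68 in siMAPK14 and fell by 1.89 in siMAPK8_9 (difference 2.56 ± 0.25, adjusted p = 5.45e-05). G0S2, an inhibitor of triglyceride breakdown, fell by 0.43 in siMAPK14 and rose by 4.48 in siMAPK8_9 (difference -4.92 ± 0.23, adjusted p = 1.38e-07). The other genes with the largest positive differences were MT-ND6 (3.37 ± 0.76), whose antisense position and the unstated strand of the libraries leave its reads uncertain, PXYLP1 (2.79 ± 0.32), FAT3 (2.62 ± 0.57) and CCN3, a matricellular protein (2.57 ± 0.13). Those with the largest negative differences were PLIN2, a lipid droplet protein (-4.76 ± 0.31), ARG2 (-4.83 ± 0.27) and GDF15 (-5.77 ± 0.39). SERPINB5 and JUP, both epithelial genes, were at -7.44 ± 2.11 and -8.08 ± 2.21, and without siMAPK8_9 replicate 2 at -1.08 (adjusted p = 0.345) and -2.17 (adjusted p = 0.107). Leaving out any 1 library of siMAPK14 or of a control also ended the calls of SERPINB5 (adjusted p up to 0.0785) and JUP (adjusted p up to 0.0694), as did limma-voom (adjusted p = 0.149 and 0.161) and the replicate block (adjusted p = 0.174 and 0.171).

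The levels behind these differences lay apart in the controls more than in the knockdowns for many genes. In a joint fit of all 12 libraries, DUSP1 averaged 273 CPM in the control of siMAPK14, 277 in siMAPK14, 43.5 in the control of siMAPK8_9 and 318 in siMAPK8_9. In the same order GDF15 averaged 95.1, 98.3, 1.43 and 79.8 CPM, G0S2 119, 86.5, 2.97 and 65.2 CPM, and DDIT3 121, 362, 23.4 and 360 CPM. AP-1 and immediate-early genes lay higher in the control of siMAPK14 than in the control of siMAPK8_9 by a median of 1.25, with 21 of 27 higher and 1 lower by the test, and differed by -0.05 between the knockdown groups. Inflammatory genes differed by 1.18 between the controls and 0.06 between the knockdowns, and ATF4 and unfolded protein genes by 0.77 and 0.04. Glycolysis and hypoxia genes lay 0.56 higher in the control of siMAPK14, with 21 of 35 higher by the test, and 0.62 lower in siMAPK14 than in siMAPK8_9 (-0.62). MMP3 averaged 22.9 CPM in the control of siMAPK14, 110 in siMAPK14, 62.4 in the control of siMAPK8_9 and 21.7 in siMAPK8_9. The batch labels part the experiments in the same way, so control siRNA group and batch cannot be told apart.

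**Figure D4:**
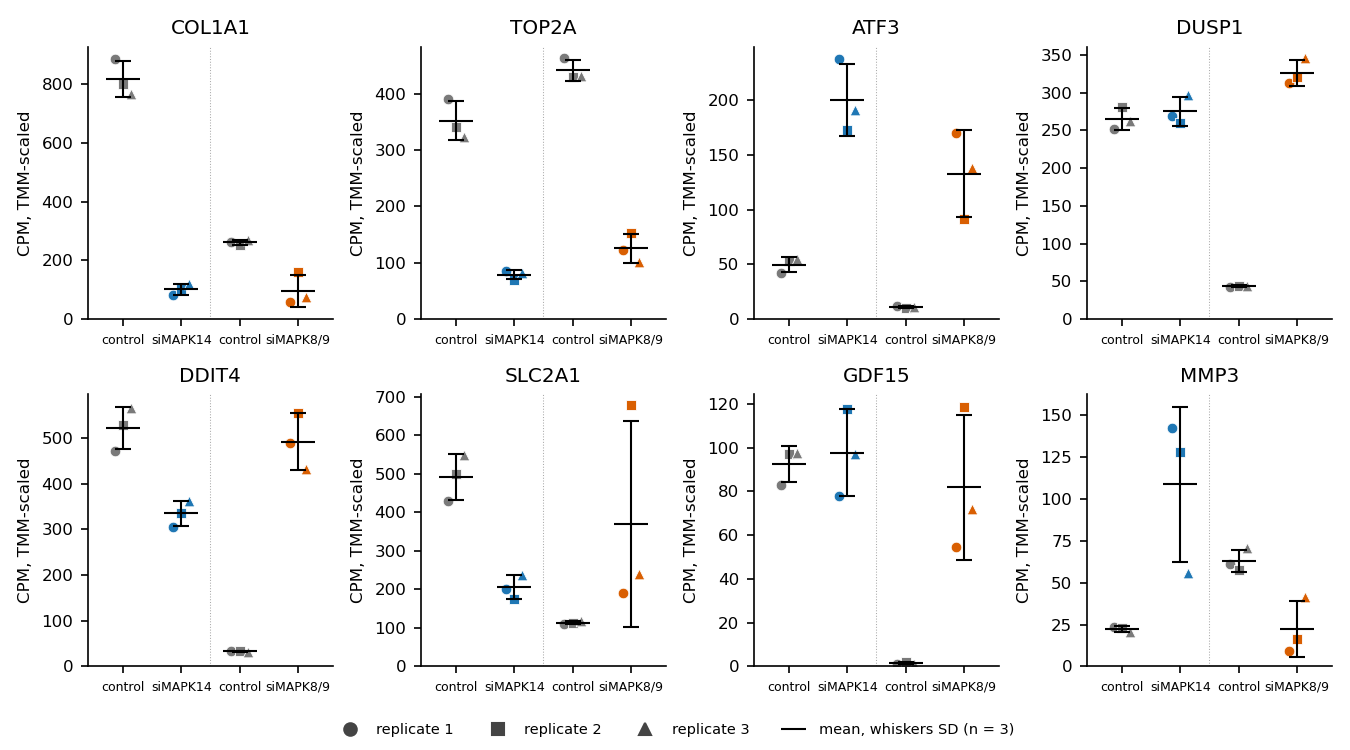
TMM-scaled CPM of COL1A1, TOP2A, ATF3, DUSP1, DDIT4, SLC2A1, GDF15 and MMP3 in each library (points), with group mean and SD, for the 4 groups. DUSP1 averaged 265 CPM in the control of siMAPK14 and 44.0 CPM in the control of siMAPK8_9, and 275 and 326 CPM in the knockdowns.

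In the test of the difference 2169 of 13648 genes passed (938 higher and 1231 lower), 1017 of them at least 2-fold. Without siMAPK8_9 replicate 2 the count was 5205 (2807 higher and 2398 lower), of which 2134 were among the 2169; leaving out any 1 control library gave 1266 to 1371 (1371, 1282 and 1266 for the control of siMAPK14, 1330, 1280 and 1268 for the control of siMAPK8_9), and total-count scaling gave 1028 (184 higher and 844 lower).

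Across the 12869 genes tested in both experiments, the fold changes of the knockdowns were correlated (Pearson r = 0.610, Spearman rho = 0.688, across genes, which are not independent replicates). COL1A2, a chain of collagen I, fell in both (-1.97 ± 0.11 and -1.54 ± 0.29, and in siMAPK8_9 -0.98 with the length trend removed). NFIX, TEAD1, UHRF1 and TOP2A also fell in both, while ATF3, FOS, DDIT3, GADD45A and SQSTM1 rose in both. Of 5128 genes that passed in both experiments 4881 (95.2%) changed in the same direction, 2551 higher and 2330 lower against 1018 and 1053 if the calls were independent, and 247 in opposite directions. With the length trend removed r was 0.454, and 2607 of 2911 shared genes (89.6%) had the same direction. Between single knockdown libraries r was 0.547 to 0.592 without siMAPK8_9 replicate 2 and at most 0.420 with it.

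**Figure D5:**
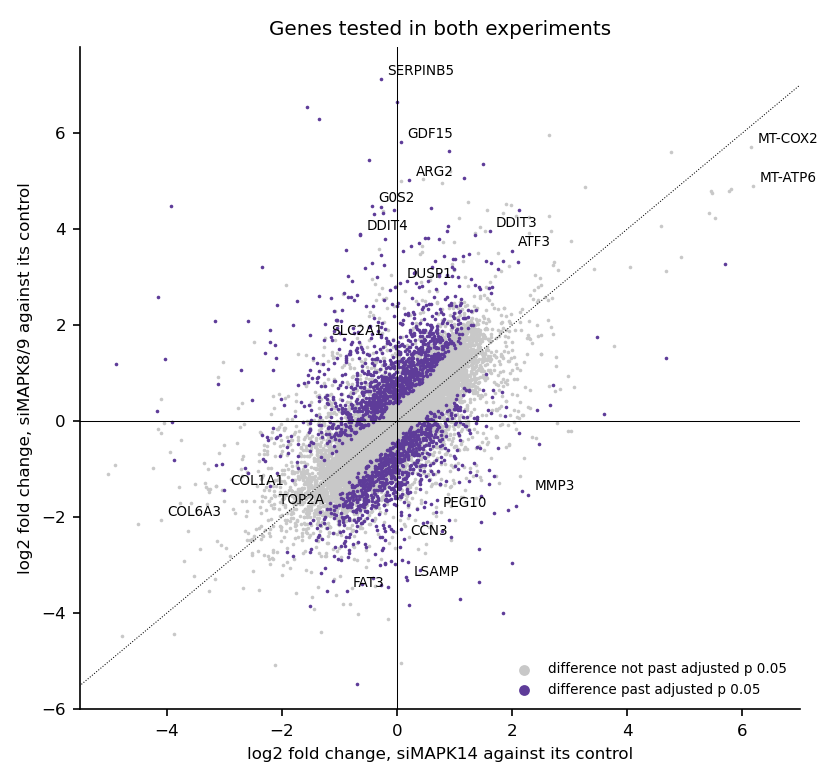
Log2 fold change in siMAPK14 (horizontal axis) against that in siMAPK8_9 (vertical axis), 1 point per gene tested in both, with purple points where the difference passed an adjusted p of 0.05. The cloud runs along the diagonal (r = 0.610), and GDF15 (difference -5.77), G0S2 (-4.92) and MMP3 (3.82) lie away from it.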

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

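The tests of the control levels, of replicate 2 as the source of opposite changes, of total-count scaling, of a mixture with control cells and of epithelial RNA were chosen only after the results they measure were seen; the other tests in this part were written before.

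A gene list and 3 of the named genes passed the test in opposite directions in the 2 knockdowns and also passed the test of the difference itself; with an estimated correlation the list passed none of them (adjusted p = 0.568 in siMAPK14, 0.720 in siMAPK8_9 and 0.135 for the difference). The glycolysis and hypoxia list differed by a median of -1.46 log2 units, MMP3 by 3.82, PEG10 by 2.56 and G0S2 by -4.92. Replicate 2 of siMAPK8_9 is not the whole cause, since without it the median difference of the list was -1.09. Different starting levels in the control groups could account for part of it: 18 of 35 list members (51.4%) differed more between the controls than between the knockdowns, which does not decide, and for G0S2 the controls differed by 5.32 log2 units and the knockdowns by 0.40 ± 0.15. A different effect of losing p38-alpha and of losing JNK1 and JNK2, which the design names, stays open for MMP3 and PEG10, where the knockdowns differed by 2.37 ± 0.44 and 1.13 ± 0.18 (the controls by -1.45 and -1.43), and for the list, where they differed by -0.62. The differences between the knockdown groups also lie across the batches, and PEG10 differed more between the controls than between the knockdowns. Control group and batch cannot be told apart, because each batch holds 1 control group, while a batch shift common to a control and its knockdown would cancel in the difference.

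Mitochondrially encoded transcripts were higher in both knockdowns. A shift made by the scaling is argued against, because under total-count scaling the medians of the 13 genes were 4.67 in siMAPK14 and 3.48 in siMAPK8_9. These medians largely restate the higher share of counts reported above, so they are not separate evidence. A coordinated rise that includes nuclear-encoded mitochondrial genes stays open. The nuclear oxidative phosphorylation list was set against random lists matched on transcript length and expression. Its median lay at percentile 100 in siMAPK14 and 99.71 in siMAPK8_9. The random genes were drawn independently, so these percentiles ignore correlation between list members. The excess over the random lists was small beside the mitochondrial change: 1.02 against a random median of 0.71 in siMAPK14, and 1.34 against 1.02 in siMAPK8_9. Cytosolic ribosomal protein genes, which are not mitochondrial, rose by medians of 1.12 and 1.58, so a rise of this size was not particular to mitochondrial genes. Loss of cytoplasmic messenger RNA relative to mitochondrial RNA, in damaged cells or in handling, also remains open: the nuclear-encoded counts reached at most 18.34 M (mega) in a knockdown library, but the sequenced depth sets that total as well.

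Replicate 2 of siMAPK8_9 stood apart from replicates 1 and 3. A mixture with control cells or a failed knockdown is argued against, since MAPK8 and MAPK9 lay further from the control in that library than in the others (-12.3% and -17.9% of the distance from control to knockdown left). A weaker form of the RNA state seen in the other knockdown libraries is consistent with the data, as the difference of replicate 2 from the other replicates ran against the siMAPK14 effect across genes (r = -0.415). RNA from an epithelial cell type may also be present: of 46 markers 40 lay under 10 CPM in the other 5 libraries of the experiment, and 40 of these 40 (100%) lay at least 2-fold above them in replicate 2, as did 34 of the 34 not seen beforehand. KRT14, KRT17 and KRT5 led with 409, 292 and 240 CPM, 12 of the 46 markers were at 1 CPM or more in the controls, and replicates 1 and 3, set against the rest with replicate 2 left out, had 3 and 5 such markers. The other 6 markers, not low elsewhere, went both ways in replicate 2. LAMB3, KRT18 and ITGB4 lay at least 2-fold above the other libraries of the experiment, and PERP less than 2-fold above (171 against at most 97.4 CPM). DSG2 (60.4 against up to 95.7 CPM) and GRHL2 (10.5 against up to 16.1 CPM) did not lie above them. The design sets no group apart within siMAPK8_9, so no biological explanation drawn from it was tested.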

How the results depend on the processing

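The alternatives that remove a length or GC trend, thin the counts or leave out the mitochondrial genes were tests chosen after the data were seen. The counts of genes kept within 1.5 times of the reported value under every other factor, filter, tool and trend tried, with these exceptions. For the difference between the knockdown effects the count was 1028 under total counts, 1179 with the replicate number as a block and 1368 with glmTreat at a fold of 1.2, which tests a stricter null; leaving out 1 library gave 1266 to 5205. For siMAPK8_9 leaving out 1 library gave 4509 to 9554, and for siMAPK14 6410 to 8612. The lowest counts came without a control library, and the highest for siMAPK8_9 and the difference without siMAPK8_9 replicate 2. With the length trend removed the counts were 6060, 4941 and 2498, and with the replicate block 7474, 6058 and 1179. Similar counts could hold partly different genes. Under total counts 5557 of the 7899 genes of siMAPK14 passed again, 4752 of them in the same direction. For siMAPK8_9 4464 of the 6938 passed again, all in the same direction. The 12, 12 and 10 lists called by camera in siMAPK14, siMAPK8_9 and the difference became 0, 0 and 0 with an estimated correlation, and fry, which asks another question, gave 22 in siMAPK14 (18 and 9 in the others). Leaving out 1 library gave 11 to 12, 10 to 13 and 9 to 11 lists. The correlation across genes was 0.778 for genes of at least 10 CPM and 0.454 with the length trend removed, and 0.531 to 0.619 with 1 library left out. The falls of MAPK14, MAPK8 and MAPK9 passed under all alternatives run for them.

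Named genes were refitted under DESeq2, limma-voom, RLE factors, the replicate block, removal of the length trend and without each library, but not under total-count scaling. A turn of direction was counted only for the 385 of 428 results that passed the threshold. Of 5431 alternative values 5030 counted as unchanged on these terms, 356 lost the call, 33 gained it and 12 turned direction, all 12 with the length trend removed. In siMAPK14 these were GLUL 0.37, SPAG9 0.00080, S100A6 -0.045, MT2A -0.35, THRB 0.050, TIMP1 -0.14 and HSPE1 -0.037, and in siMAPK8_9 THRB 0.33, BAX -0.0018, FDPS -0.017, RPS25 -0.13 and GABARAPL2 -0.025 (log2). Beyond removal of the length trend, the cause of these changes was not tested. Little pairing by replicate number showed in the residuals of control and knockdown libraries. Libraries of the same number had r of -0.0257 to 0.0296, and those of different numbers -0.0219 to 0.0280. The same-number r was the highest for each knockdown library in siMAPK14 and the lowest for each in siMAPK8_9. These values cannot show whether libraries were paired by design. The smallest library, siMAPK8_9 replicate 3, held 9246294 counts, and after thinning every library to the total of the smallest, mitochondrial counts included, 7314 and 6557 genes passed in siMAPK14 and siMAPK8_9, with r = 0.687.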

Other observations

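The test of a shared RNA state and all counts of other splits were written before their results were seen; the comparison of control levels was a test chosen after.

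Further gene lists were tested in both knockdowns. In siMAPK14, of 28 lysosome and autophagy genes 16 rose and 4 fell (17 and 4 adjusted over the list alone), with SQSTM1, an autophagy receptor, rising from 1586 ± 74.3 to 4187 ± 166 CPM and MAP1LC3B by 1.13 ± 0.06. The list passed camera (adjusted p = 0.0333, and adjusted p = 0.505 with an estimated correlation), but not without siControl_MAPK14_set replicate 2 or siMAPK14 replicate 3 (adjusted p = 0.0526 and 0.0728) or with the length trend removed (adjusted p = 0.276), when its median of 0.27 was 0.16. Under total-count scaling, which lowers all genes alike, the median was -0.49, still 0.30 above that of all genes. In siMAPK8_9 12 of 28 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.720 with an estimated correlation), and the call ended without siMAPK8_9 replicate 2 (14 and 7, adjusted p = 0.133) and with the length trend removed (adjusted p = 0.365). There the median of 0.21 was 0.05 with the length trend removed, and -0.44 under total-count scaling, 0.26 above that of all genes. Of 24 p53 targets 9 rose and 4 fell in siMAPK14 and 12 rose and 4 fell in siMAPK8_9 (the same counts adjusted over the list alone; camera adjusted p = 0.239 and 0.157, the latter 0.0336 with the length trend removed). Among them CDKN1A, the cell cycle inhibitor p21, rose by 0.96 ± 0.09 and 3.03 ± 0.27. Notch genes went both ways, 3 higher and 8 lower of 17 in siMAPK14 and 2 and 5 of 17 in siMAPK8_9 (4 and 8, and 2 and 5 adjusted over the list alone; camera adjusted p = 0.687 and 0.576). NOTCH1 fell by 1.81 ± 0.09 (by 1.17 with the length trend removed) and HES1 rose by 1.62 ± 0.16 in siMAPK14. Wnt targets were lower in 6 of 13 cases and 7 of 15 (5 and 7 adjusted over the list alone; camera adjusted p = 0.0731 and 0.0951; 0.0379 in siMAPK14 without siMAPK14 replicate 3 and 0.0279 in siMAPK8_9 with the length trend removed), with DKK1 at -1.96 ± 0.15 in siMAPK14 and AXIN2 at -2.74 ± 0.35 in siMAPK8_9. In siMAPK8_9 without replicate 2 the counts higher and lower were 10 and 8 for p53 targets, 4 and 7 for Notch genes (median -0.39 against -0.15) and 1 and 9 for Wnt targets.

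Markers of other cell types gave no list past camera within an experiment. Of 16 pericyte and fibroblast markers 3 rose and 11 fell in siMAPK14 and 6 rose and 4 fell in siMAPK8_9 (the same counts adjusted over the list alone; camera adjusted p = 0.0682 and 0.798). ACTA2, the smooth muscle actin, rose from 39.8 ± 2.41 to 319 ± 186 CPM in siMAPK8_9. Between the knockdown effects 5 of 18 differed, all lower (7 adjusted over the list alone; 1 higher and 8 lower without siMAPK8_9 replicate 2; median -1.01, camera adjusted p = 0.00744, and adjusted p = 0.496 with an estimated correlation). The counts of genes higher and lower were 3 and 4 of 15 in siMAPK14 and 4 and 4 of 15 in siMAPK8_9 for neuronal genes, 3 and 2 of 9 and 1 and 2 of 10 for inner retinal neurons, 1 and 2 of 5 and 2 and 1 of 5 for the retinal pigment epithelium, and 2 and 2 of 5 and 0 and 0 of 5 for astrocytes and oligodendrocytes. They were 1 and 1 of 8 and 0 and 2 of 6 for endothelium, 2 and 1 of 5 and 2 and 0 of 4 for microglia and macrophages, and 1 and 1 of 3 in both for photoreceptors. Adjusted over the list alone these counts were the same, except 0 and 1 for endothelium in siMAPK14 and 2 and 2 and 3 and 0 for microglia and macrophages; camera gave adjusted p = 0.372 to 0.954 for those of these lists with at least 5 tested members. Leaving out siMAPK8_9 replicate 2 gave 6 and 7 in siMAPK8_9 for pericytes and fibroblasts, 3 and 6 for neuronal genes, 2 and 4 for inner retinal neurons, 1 and 1 for astrocytes and oligodendrocytes, 0 and 3 for endothelium and 2 and 1 for microglia and macrophages. Matrix proteases and inhibitors were higher in 3 and lower in 7 of 14 genes in siMAPK14 and 2 and 3 of 17 in siMAPK8_9 (3 and 7, and 2 and 1 adjusted over the list alone; camera adjusted p = 0.222 and 0.379, the former 0.0378 with the length trend removed), and cholesterol synthesis genes 8 and 6 of 24 and 11 and 3 of 24 (8 and 6, and 11 and 4 adjusted over the list alone; camera adjusted p = 0.437 and 0.169; 5 and 4, and 5 and 2 with the length trend removed). Without siMAPK8_9 replicate 2 the siMAPK8_9 counts were 2 and 11 for the proteases (median -1.31 against -0.72) and 12 and 9 for cholesterol synthesis. In siMAPK8_9 5 of 36 interferon-stimulated genes rose and 16 fell, 3 of 30 receptor tyrosine kinase genes rose and 11 fell, and 7 of 16 heat shock genes rose and 3 fell (5 and 17, 3 and 11, and 7 and 3 adjusted over the list alone; camera adjusted p = 0.0917, 0.114 and 0.365). The interferon list passed without siControl_MAPK8_9_set replicate 2 (adjusted p = 0.0367) and with the length trend removed (adjusted p = 0.0235), and the receptor tyrosine kinase list without siMAPK8_9 replicate 2 (5 and 18, median -0.93 against -0.52, adjusted p = 0.0387). Without that library the interferon and heat shock counts were 8 and 18 and 8 and 5. Between the knockdown effects the nuclear oxidative phosphorylation list (median -0.33), the ribosomal list (-0.51), the heat shock list (0.32) and the mitochondrial list (1.08) also passed camera (adjusted p = 0.00659, 7.27e-06, 0.0165 and 0.00659), and not with an estimated correlation (adjusted p = 0.899, 0.899, 0.684 and 0.899). The oxidative phosphorylation call ended without siMAPK8_9 replicate 1 or 3 (adjusted p = 0.0846 and 0.187) and with the length trend removed (median -0.12, adjusted p = 0.431), whereas without siMAPK8_9 replicate 2 the list lay further apart (median -0.50, with 24 genes lower against 2, adjusted p = 5.63e-10). The heat shock call ended without siMAPK8_9 replicate 2 (adjusted p = 0.172) and with the replicate number as a block (adjusted p = 0.0525). The ribosomal median was -0.17 with the length trend removed, and the 1 of 52 genes lower by the test became 52 without siMAPK8_9 replicate 2, when the mitochondrial median was 0.66.

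A hypothesis is that both knockdowns share an RNA state marked by the mitochondrial share, which would make their fold changes alike across genes. Within groups, libraries with a higher share should then lie further along the other knockdown's effect. The covariance had that sign, with slopes of 0.522, 0.484 and 0.429 for siMAPK14 libraries at 45.0%, 41.0% and 32.1%, and 0.937, 0.944 and 0.491 for siMAPK8_9 libraries at 36.9%, 35.0% and 8.93%. In siMAPK8_9 that sign rested on replicate 2, the library that also held epithelial transcripts. Replicates 1 and 3 ran the other way by a small margin (0.937 at 36.9% and 0.944 at 35.0%). The one-sided exact permutation p was 0.0556 over 36 orders, the smallest possible being 0.0278, so these libraries may share such a state but the test does not decide.

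The control groups differed from each other in 3045 genes and the knockdown groups in 1799, across batches. Of the 2169 genes past the test of the difference 1305 (60.2%) differed more between the controls, against 51.7% of all genes tested. Across genes the difference of the controls and that of the knockdowns had r = 0.103.

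Other splits of the libraries were counted for each comparison. For siMAPK14 1 of 10 splits, the real one, gave 7899 genes and the highest other 0, and for siMAPK8_9 1 of 10 gave 6938 and the highest other 0; 10 splits are too few for a share under 0.05. For the difference 9 of 100 drawn regroupings of 200 gave at least the real 2169, with the highest other at 4771, so chance is not excluded by this count. All 8 others keep the real split of 1 experiment, 6 of them that of siMAPK8_9 and 2 that of siMAPK14, and so carry that knockdown's own effect, and the 80 drawn that keep neither real split called at most 0 genes. For the correlation across genes 1 of 100 pairs of splits, the real one, reached an absolute r of 0.610, and the highest other was 0.600. With neither real split the absolute r reached 0.518, with a median of 0.234, so large values also arose without the real groups. The real pair ranked first by a small margin, and this count does not decide whether the 2 effects are related.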
